A study of Arabidopsis thaliana with 6 samples.

How the data were processed

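Siliques of Col-0 and of the mee45-1 mutant were compared 4 days after pollination, with 3 libraries of each genotype, per the labels. The labels name the tissue both as silique and as seed, and mention both 3 repeats and duplicate collection; the material is called silique here and n is taken as 3. Nothing in the sources used here says whether the repeats came from separately grown plants, so p-values measure the spread between these libraries, which may be technical.

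Per the labels' protocols, RNA was extracted with Trizol and sequenced as paired ends on an Illumina instrument. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, TopHat2 2.0.3.12, Cufflinks, RSEM and edgeR and the genome build TAIR10, without the role of each. The deposited estimated counts are the authors' means over the libraries of a genotype: 95.8% of the Col-0 values and 95.9% of the mee45 values were whole multiples of a 3rd within 0.01 counts. The deposited FPKM values are likewise the authors' means per genotype. The authors' deposited table of the comparison gives log2 fold changes, p-values and adjusted p-values for 25434 genes; the 6174 other genes had 0 counts in both genotypes. Its log2 values equal the log2 ratio of the mean FPKM with zeros set to 0.001, and its adjusted p-values equal a Benjamini-Hochberg adjustment over those 25434 genes. Which option of edgeR gave the p-values is not given in the sources used here.

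The design fixed before the data were examined was a quasi-likelihood test of counts per library with gene set tests by camera. It could not be run on genotype means, and no new test between the genotypes was made. Calls therefore rest on the adjusted p of the authors' deposited table under 0.05, and the tests described here start from those calls. Log2 fold changes were computed from mean FPKM. For a gene at 0 in a genotype, the fold is a bound against a floor of 3 counts over that group, scaled by total counts, and no fold is given for a gene at 0 in one genotype and at or under the floor in the other. Such genes, YUC2, YUC5, YUC7 and PR1 among list members, are listed at 0 and enter list medians as 0. For genes with 1 to 3 summed counts, ratios at equal total counts are given with exact 95% binomial counting intervals. PCR reads without molecular identifiers are not independent, so these intervals and floors cover counting error only.

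Gene lists, 25 with 344 genes, were fixed before the data were examined, and 2 symbols that the reference pairs with another identifier were left out. For each list of at least 4 tested genes, members called higher and lower were counted over all genes and after a Benjamini-Hochberg adjustment of the authors' p over the list alone. The list median was placed among the medians of 10000 random lists of the same size drawn within 20 bins of mean count. This placement describes these libraries and is not a test, since genes are not replicates. GO and KEGG terms as deposited with the table, of 10 to 500 tested genes, were tested by a one-sided Fisher's exact test for each direction. The background was the tested genes with an annotation of that kind, and p was adjusted over terms and directions. Fisher's test counts genes as independent, so where genes change together its p-values may be too small. Of 2077 GO process terms, 53 were enriched among higher and 107 among lower genes.

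Named genes are MEE45 and ANT, the 10 largest increases and 10 largest decreases among called genes with a mean CPM of at least 2 in the higher genotype, and per list up to 3 called members with the smallest p, or the 1 with the smallest p where none was called. The further condition that the libraries of the genotypes do not overlap could not be applied. Genes at 0 were ranked at their bound, a choice made after values were seen; ranking by the log2 values of the authors' deposited table names the same 10 increases but shares 4 of the 10 decreases. List members named beyond this rule were chosen after their values were seen.

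Coordinates of MEE45 are from the TAIR10.1 reference annotation, and 30622 identifiers matched that reference. The steps were checked on simulated data for this comparison. With random calls among 15529 annotated genes, 0 GO terms were called, and 10 of 10 terms given extra calls were recovered. Those calls were placed independently of each other, so this check does not cover genes that change together. Among 25434 genes, 2 of 100 random lists of 15 expressed genes fell outside the middle 95% of their random lists. When every member was shifted by 0.5 on the log2 scale, 100 of 100 lists were placed above it. Such a shift is large beside the spread of random list medians, so this recovery says little about smaller or mixed changes. The lists were drawn at random, so this check does not cover lists of genes that change together either. Alternatives covered thresholds, scaling by total counts or by the median ratio, pseudocounts of 1 and 0.1, a minimum mean count of 10, list medians over genes with a fold only and the enrichment background. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.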

Results

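PolyA RNA was sequenced from Arabidopsis siliques, the fruits that enclose the developing seeds, collected 4 days after pollination from the wild-type accession Col-0 and from the mee45-1 mutant. The 6 libraries comprised 3 of each genotype. The values used here are the authors' means over the 3 libraries of a genotype, as estimated read counts and as FPKM, for 31608 genes and loci. Mean depth per library was 20242476 counts in Col-0 and 20530953 in mee45. No spread between libraries can be computed from genotype means, so fold changes below carry no replicate SD, and intervals, where given, cover counting error only. A gene is said to have risen or fallen in mee45 only where its adjusted p in the authors' deposited table was under 0.05, and log2 fold changes are of the ratio of mean FPKM, mee45 over Col-0, with rises given on the log2 scale.

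The first question was whether the targeted gene was reduced in the libraries labelled mee45. MEE45 (AT4G00260), a gene of 7 annotated exons on chromosome 4 from 114971 to 117051 in TAIR10.1, had 62 counts summed over the Col-0 libraries and 3 over the mee45 libraries. The mee45 level was 4.77% of the Col-0 level at equal depth, with an exact 95% counting interval of 0.958% to 14.6%. Its adjusted p in the authors' deposited table was 4.34e-06. Even in Col-0 the transcript was scarce, at a mean of 0.65 FPKM. ANT (AT4G37750), which encodes AINTEGUMENTA, a regulator of integument growth and organ size, had mean counts of 170.3 in Col-0 and 113.7 in mee45. The ANT log2 fold change was -0.63, and the gene did not pass the test, with an adjusted p of 0.219 in the authors' deposited table.

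The comparison of the genotypes gave 1696 genes higher and 2326 genes lower in mee45 among the 25434 genes tested, so that 57.8% of the changed genes were lower. The strongest changes were decreases. A change of at least 4-fold was seen for 369 of the lower genes and 80 of the higher genes, and a change of at least 10-fold for 122 lower and 17 higher genes. The median log2 fold change of the 20267 genes with 10 or more mean counts in both genotypes was 0.0051, and the 7 reference genes, among them ACT2, UBQ10 and PP2AA3, had a median of 0.05 with 0 members past the test over all genes and 0 adjusted over the list alone.

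**Figure D1:**
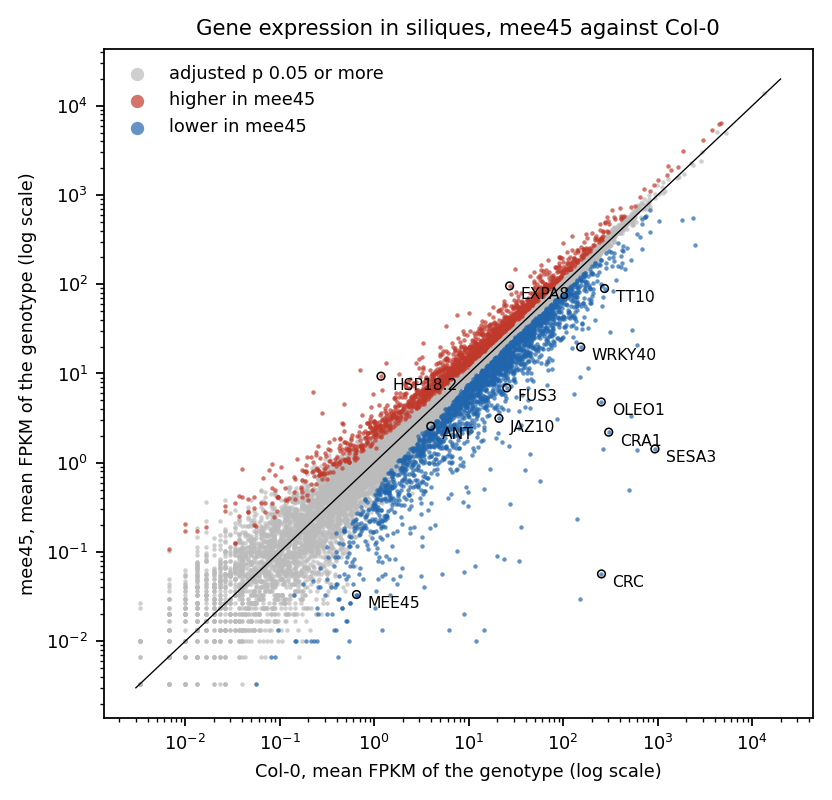
Mean FPKM of each gene in mee45 (vertical axis, log scale) against Col-0 (horizontal axis, log scale), with genes coloured by the authors' adjusted p and direction; the 1379 tested genes at FPKM 0 in either genotype are not drawn. Those drawn of the 2326 lower genes reach much farther from the diagonal than those drawn of the 1696 higher genes, and CRC, CRA1 and SESA3 lie far below it.

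Seed storage and maturation genes fell as a group. All 17 tested members of this list were lower in mee45, over all genes tested and adjusted over the list alone, with a median log2 fold change of -5.72, below that of every random list of like expression (0% of 10000 lists lay lower). Together they took 0.352% of all counts in Col-0 and 0.0154% in mee45. The cruciferin genes encode the 12S globulins of the seed. In Col-0 siliques labelled 4 days after pollination, SESA3 had a mean of 936 FPKM and CRC of 254 FPKM. CRC (AT4G28520) went from a mean of 8978 counts to 2, and CRB (AT1G03880) from 14354 summed counts to 3, which is 0.0206% of the Col-0 level at equal depth (exact 95% counting interval 0.00425% to 0.0602%). CRA1 (AT5G44120) had a log2 fold change of -7.11. The 2S albumin genes SESA2 (AT4G27150), SESA3 (AT4G27160) and SESA4 (AT4G27170) had log2 fold changes of -8.77, -9.36 and -9.97, though they are similar neighbours and the split of reads among them is uncertain. OLEO1 (AT4G25140), an oleosin that coats oil bodies, had a log2 fold change of -5.72, and FAE1, the elongase that makes very-long-chain fatty acids of seed oil, -3.71. Regulators of the programme moved less, with ABI3 at -1.99, and the acyltransferase gene DGAT1 was at -0.53. Lipid particle had the smallest adjusted p of the cellular components among lower genes, with 22 of its 37 tested genes lower against 3.58 expected (Fisher's exact test over terms, adjusted p = 3.67e-11).

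**Figure D2:**
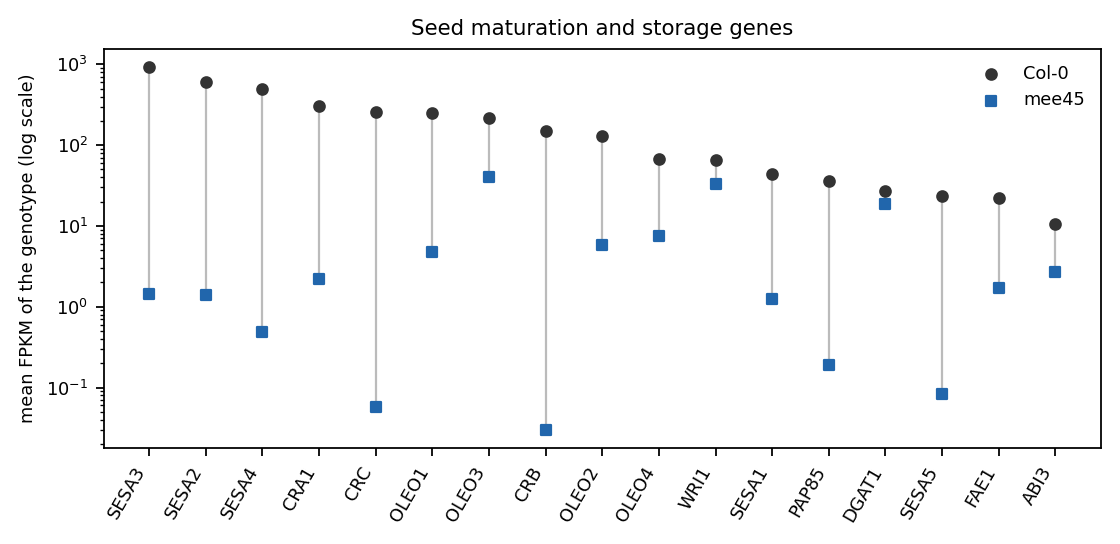
Mean FPKM (log scale) of the 17 tested seed maturation and storage genes in Col-0 (circles) and mee45 (squares), ordered by the Col-0 level; no error bars are drawn because only genotype means were used. Every gene lies lower in mee45, by a log2 fold change from -0.53 for DGAT1 to -12.28 for CRB.

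Of 18 tested embryo markers, 6 fell, 1 rose and 11 did not pass the test, and the counts adjusted over the list alone were also 6 and 1. The list's median was -0.36, with 0.85% of random lists lower, and with log2(FPKM + 1) it was -0.12, inside the middle 95% of random lists. FUS3 (AT3G26790), a B3-domain regulator of maturation, and L1L (AT5G47670), a LEC1-like CCAAT-binding factor, both had a log2 fold change of -1.88. LEC1, LEC2, WOX8 and WOX9 fell with values from -0.74 to -0.48. STM (AT1G62360), which maintains shoot meristems, rose by 0.80.

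Of 21 tested endosperm markers, 8 rose, 3 fell and 10 did not pass the test over all genes, and adjusted over the list alone 10 rose and 4 fell, with a median of 0.38 that exceeded that of 100% of random lists to the precision of 10000 draws. The type I MADS-box genes AGL36 (AT5G26650) and AGL62 (AT5G60440) rose by 1.69 and 1.01, the latter being a repressor of endosperm cellularization. ZOU (AT1G49770) and ALE1 (AT1G62340), which act in endosperm breakdown and embryo cuticle formation, had log2 fold changes of -0.93 and -0.82. Among zygotic seed size regulators, 3 of 8 rose and 1 fell by either adjustment, with a median of 0.74 above that of 99.98% of random lists, and with log2(FPKM + 1) it was 0.16, inside their middle 95%. CKX2 (AT2G19500), a cytokinin oxidase, and MINI3 (AT1G55600), a WRKY factor of the HAIKU pathway, rose by 0.76 and 0.73, and AGL62 and MINI3 also stand on the endosperm list. Maternal seed size regulators changed little, with only CYP78A6 (AT2G46660) of 13 higher by either adjustment, at 1.21, and a median of 0.07.

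The seed coat lists moved apart. Mucilage genes fell in 13 of 18 cases, and 13 also adjusted over the list alone, with a median of -0.65 below that of every random list (0% lower). GATL5 (AT1G02720) had a log2 fold change of -1.84, MUM4 (AT1G53500), a rhamnose synthase for pectin, -1.16, and FLY1 (AT4G28370), a ubiquitin ligase, -0.90. Flavonoid genes rose in 7 of 18 cases and fell in 2, with 9 and 2 adjusted over the list alone, and their median of 0.27 exceeded that of 99.99% of random lists. TT12 (AT3G59030), a vacuolar transporter of proanthocyanidin precursors, and AHA10 (AT1G17260), a proton pump, rose by 0.95 and 0.68. TT10 (AT5G48100), the laccase that oxidizes proanthocyanidins late in seed coat browning, fell from a mean of 11372 counts to 3804, a log2 fold change of -1.61.

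Auxin genes were higher in several classes. Early auxin response genes rose in 11 of 32 cases with 0 lower, and adjusted over the list alone 17 rose and 1 fell, with a median of 0.31 above that of every random list (100%). The Aux/IAA repressors IAA4 (AT5G43700), IAA17 (AT1G04250) and IAA7 (AT3G23050) rose by 1.00, 0.85 and 0.60. Auxin transport genes rose in 8 of 16 cases, or 9 adjusted over the list alone, with a median of 0.46 (100%). PIN3 (AT1G70940), PIN7 (AT1G23080) and LAX3 (AT1G77690), which carry auxin out of or into cells, rose by 0.73, 0.76 and 0.97. Auxin biosynthesis genes went both ways, with 2 higher and 2 lower of 14 by either adjustment and a median of 0.02, or 0.17 over the 11 members with a fold, as YUC2, YUC5 and YUC7 are listed at 0. TAR2 (AT4G24670) and YUC6 (AT5G25620) rose by 0.53 and 0.80, whereas YUC4 (AT5G11320) had a log2 fold change of -2.03. Response to auxin was enriched among higher genes, with 61 of 350 annotated genes higher against 26.6 expected (Fisher's exact test, adjusted p = 1.80e-07).

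Cell wall expansion genes had the highest share of higher members of any list. Of 12 tested members, 11 rose, and adjusted over the list alone 11 rose and 1 fell, with a median of 0.73 (100% of random lists lower). The expansins EXPA8 (AT2G40610), EXPA3 (AT2G37640) and EXPA6 (AT2G28950), which loosen walls during growth, rose by 1.82, 1.73 and 1.34. Cell wall organization had the smallest adjusted p of the processes among higher genes, with 89 of 492 genes against 37.4 expected (adjusted p = 6.34e-12 by Fisher's exact test). In the gibberellin list 3 of 11 rose and 2 fell, or 4 and 2 adjusted over the list alone, with a median of 0.32 above 98.8% of random lists. The gibberellin-responsive GASA4 (AT5G15230) rose by 1.36, while GA20OX3 (AT5G07200), a biosynthetic oxidase, and GA2OX6 (AT1G02400), which inactivates the hormone, had log2 fold changes of -1.62 and -1.83. Of 4 brassinosteroid genes only DWF4 (AT3G50660) rose, by 0.46, or 2 adjusted over the list alone, with a median of 0.16. Cytokinin response genes had 1 of 8 lower by either adjustment, ARR5 (AT3G48100) at -0.92, and a median of 0.07.

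Most mitotic cell cycle genes, 19 of 21, did not pass the test over all genes. KNOLLE (AT1G08560), the syntaxin of the forming cell plate, and HINKEL (AT1G18370), a cytokinetic kinesin, were the 2 that fell, at -0.78 and -0.37. Adjusted over the list alone, 7 fell. The median of -0.35 lay above that of only 0.01% of random lists. G1 and S phase genes had 1 of 19 higher by either adjustment, CYCD1;1 (AT1G70210) at 0.76, with a median of 0.10.

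Jasmonate and defence genes had 5 of 12 members lower and 1 higher by either adjustment, with a median of -0.79 below every random list (0%), or -1.44 over the 11 members with a fold, as PR1 is listed at 0. WRKY40 (AT1G80840) had a log2 fold change of -2.95, and the jasmonate signalling repressors JAZ5 (AT1G17380) and JAZ1 (AT1G19180) -2.38 and -1.45, whereas VSP1, a vegetative storage protein gene induced by jasmonate, rose by 0.90. Response to chitin, with 65 of 125 genes lower against 12.9 expected (Fisher's exact test, adjusted p = 4.51e-28), had the smallest adjusted p of the processes among lower genes, and response to wounding had 70 of 174 lower against 17.9 expected (adjusted p = 2.97e-22 in Fisher's exact test). Cold and drought genes fell in 5 of 11 cases by either adjustment, with a median of -0.42 above 0.59% of random lists. ERD10 (AT1G20450), CBF1 (AT4G25490) and RD29A (AT5G52310) had log2 fold changes of -0.83, -1.25 and -0.51. Circadian clock genes fell in 5 of 13 cases, and adjusted over the list alone 6 fell and 1 rose, with a median of -0.31 above 0.30% of random lists. PRR9 (AT2G46790), PRR5 (AT5G24470) and LUX (AT3G46640) had log2 fold changes of -1.44, -0.86 and -0.49, and CCA1 was at -0.09 without passing the test. Heat shock genes had 2 of 6 higher, or 3 adjusted over the list alone, with a median of 0.83 (100%), HSP18.2 (AT5G59720) and HSFA2 (AT2G26150) rising by 2.98 and 2.13.

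Photosynthesis genes rose in 5 of 22 cases, or 8 adjusted over the list alone, with a median of 0.20 above 99.87% of random lists. The small subunit genes of Rubisco RBCS2B (AT5G38420), RBCS1B (AT5G38430) and RBCS1A (AT1G67090) rose by 0.73, 0.55 and 0.48, and since these copies are similar in sequence the split of reads among them is uncertain. The light-harvesting genes on the list did not pass the test over all genes. Chloroplast-encoded genes, whose reads are a trace in polyA libraries, took 0.00982% of counts in Col-0 and 0.0193% in mee45, with 7 of 71 tested higher and 0 lower. Silique wall genes had 2 of 13 higher and 2 lower by either adjustment, with a median of 0.10. IND (AT4G00120) and SHP1 (AT3G58780), regulators of valve margin identity, rose by 0.69 and 0.40, whereas SHP2 (AT2G42830) fell, at -0.33. ADPG1 (AT3G57510), a polygalacturonase of pod opening, had a log2 fold change of -0.77. Pollen and anther markers had 1 of 9 tested members lower, VEX1 (AT5G62850) with mean counts of 221.7 in Col-0 and 57.3 in mee45, and adjusted over the list alone 1 lower and 1 higher, with a median of 0.39 above 98.2% of random lists, and with log2(FPKM + 1) it was 0.14, inside their middle 95%.

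**Figure D3:**
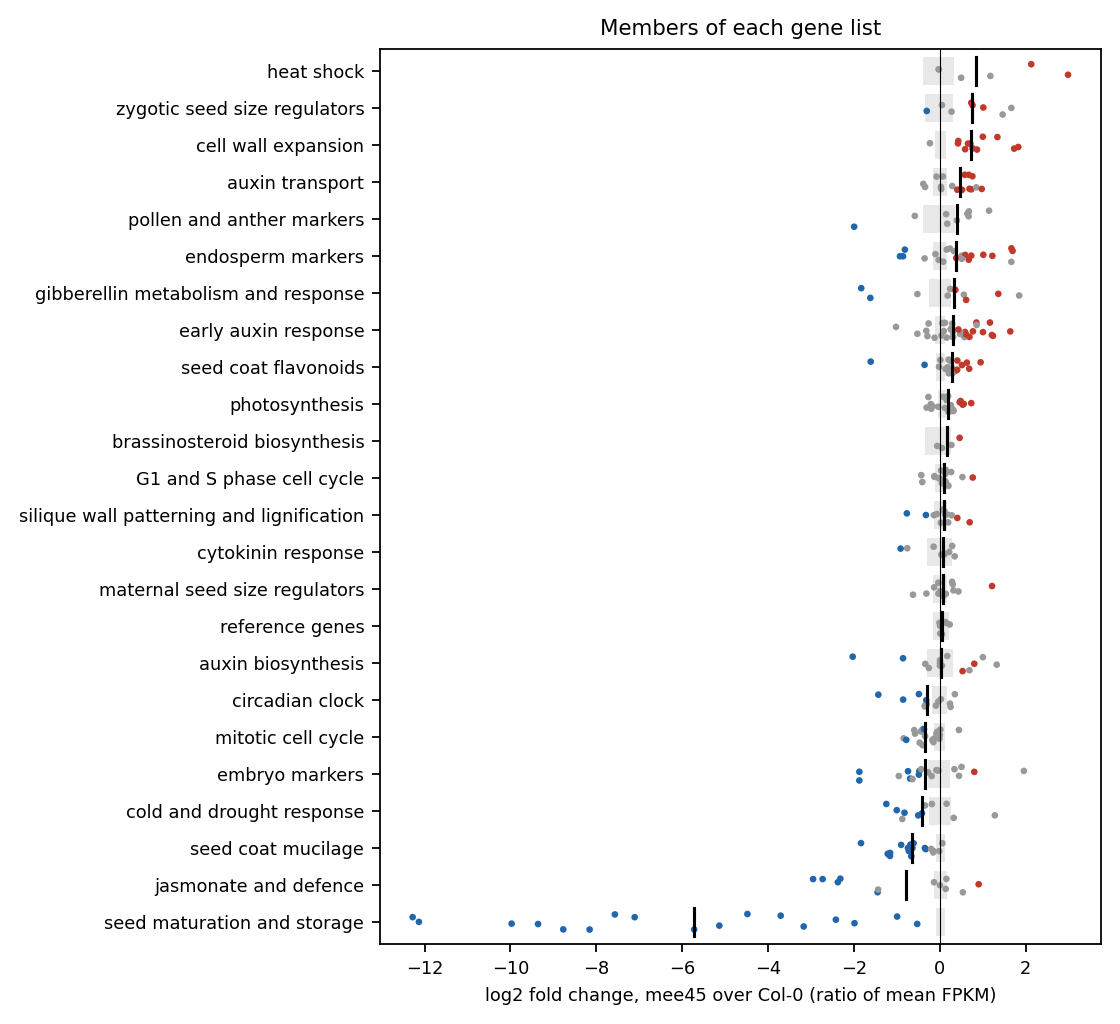
Log2 fold change of mee45 over Col-0 (horizontal axis, ratio of mean FPKM) for each tested member of the gene lists, with red for members higher and blue for members lower at an adjusted p under 0.05 in the authors' table and grey for the rest. Black bars mark list medians and pale bands the middle 95% of medians of 10000 random lists; the seed maturation list, with a median of -5.72, lies far left of its band.

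The 10 largest decreases were CRB, CRC, SESA4, SESA3 and SESA2, described above, and 5 other genes. The cruciferin-like gene AT1G03890 had 1 summed count in mee45 against 1064 in Col-0, 0.0927% of the Col-0 level (exact 95% counting interval 0.00234% to 0.517%). TIP3;1 (AT1G73190), a seed tonoplast aquaporin, had 1 count against 428, 0.230% of the Col-0 level (0.00582% to 1.29%). HSD1 (AT5G50600), a steroid dehydrogenase of oil bodies, had 1 count against 1110, 0.0888% of the Col-0 level (0.00225% to 0.496%), and its near-identical copy AT5G50700 makes the division of reads uncertain. AT1G62225, of a family of small unnamed proteins, had a log2 fold change of -9.22. PAO2 (AT2G43020) had mean estimated counts of 401.5 in Col-0 and 0.823 in mee45. Rounded down to whole summed counts, 2 against 1204, its level was 0.164% of that in Col-0 (0.0198% to 0.593%). But PAO2 shares its transcript with an upstream reading frame listed as a gene of its own, CPuORF17 (AT2G43018). That frame had mean counts of 1301 in Col-0 and 1692 in mee45, and the 2 entries together had 1703 and 1693, so no decrease of the transcript is seen. Among the 10 largest increases, the first, CPuORF21 (AT5G09672) at 4.79, is likewise an upstream reading frame of a longer transcript, AT5G09670. The frame had mean counts of 10.3 in Col-0 and 290.8 in mee45, the gene 914.0 and 772.5, and both together 924.3 and 1063, so most of this increase is absent from the sum. AT2G20870 followed at 3.96, the small heat shock gene ATHSP22.0 (AT4G10250) at 3.69 and the F-box gene AT2G44130 at 3.28. RXF26 (AT1G58430), LTL1 (AT3G04290), cPT6 (AT5G58782), AT5G45850 and the desaturase gene ADS4 (AT1G06350) had log2 fold changes of 3.23, 2.73, 2.62, 2.60 and 2.58, and HSP18.2 is given above.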

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

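Of the alternatives, the 1.5-fold thresholds and the enrichment of genes changed at least 1.5-fold were chosen before the data were examined, and all others afterwards. No paired analysis was possible because only genotype means were used, and for the same reason the planned size-factor, low-count, exact-test, DESeq2, limma, camera, replicate block and leave-one-library-out alternatives, and the overlap of the authors' calls with a new test, were not run, nor could other splits of the 6 libraries be counted. Genes higher in mee45 numbered 1696 in the main count, 1024 with a change of at least 1.5-fold, 491 with at least 2-fold, 1078 at an adjusted p under 0.01 and 2889 at an unadjusted p under 0.05. Genes lower numbered 2326, and 1125 with at least 2-fold; the remaining threshold and filter settings left both counts within 1.5 times. Scaling by total counts or by the median ratio moved no list median across the middle 95% of random lists and no named gene beyond its counting interval. These scalings could move little. The median log2 fold change of genes with 10 or more mean counts in both genotypes was 0.0051 by FPKM and 0.0059 by total counts. A pseudocount shrinks low genes by construction: MEE45 had a log2 fold change of -0.68 with log2(FPKM + 1) and -2.49 with log2(FPKM + 0.1) against -4.29. With log2(FPKM + 1), zygotic seed size regulators (median 0.16), embryo markers (-0.12) and pollen markers (0.14) came inside the middle 95%, and G1 and S phase genes (0.10) left it. Over genes with a fold only, the median of auxin biosynthesis genes was 0.17 against 0.02 and that of jasmonate and defence genes -1.44 against -0.79, and neither crossed the bounds of the middle 95%. Of 296 values for other named genes, 36 moved beyond their counting interval, all with a pseudocount, and no called gene changed direction. Depth limits MEE45 itself, with 62 and 3 summed counts.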

Other observations

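The tests of embryo regulators, of age at harvest and of oil and touch genes outside the seen terms were chosen after the results they bear on were seen, as were the terms and the gene cluster described next. The lists behind the other tests were written down before their medians were examined, but 3 of the 8 later jasmonate genes, VSP1, VSP2 and LOX2, and the enrichment of fatty acid, wounding and chitin terms had been seen by then. Glucosinolate biosynthesis was enriched among lower genes, with 21 of 33 annotated genes lower and 1 higher, against 3.39 lower expected (Fisher's exact test, adjusted p = 8.67e-11). BZO1 (AT1G65880), IMS2 (AT5G23020) and BCAT4 (AT3G19710) had log2 fold changes of -4.98, -2.13 and -1.38. Cutin biosynthesis had 11 of 20 genes higher and 2 lower, against 1.52 higher expected (adjusted p = 6.59e-06 in Fisher's exact test). GPAT8 (AT4G00400) and GPAT6 (AT2G38110) rose by 1.30 and 1.03 on the log2 scale, and the 2 lower genes were GPAT2 (AT1G02390) at -1.55 and GPAT3 (AT4G01950) at -0.73. Chlorophyll biosynthesis had 14 of 38 genes higher and 2 lower, against 2.89 higher expected (adjusted p = 4.39e-05, Fisher's exact test). GUN4 (AT3G59400) rose by 0.75, while the 2 lower genes, FC1 (AT5G26030) at -1.13 and HEMA2 (AT1G09940) at -0.81, had the largest changes among called genes of this term with at least 50 mean counts.

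A cluster of related genes on chromosome 1 fell steeply. AT1G62060 went from a mean of 36250 counts to 4131, AT1G62000 from 7351 to 48.3, AT1G62080 from 8586 to 301.2 and AT1G62220 from 3422 to 18. AT1G62210 had a mean of 161.7 counts in Col-0 and 0 in mee45, at least 164-fold lower. The division of reads among these related copies is uncertain. Genes between them were mixed. AT1G62030 rose by 0.88, ATG8C (AT1G62040), AT1G62050 and PTR6 (AT1G62200) fell with log2 fold changes of -0.45, -0.85 and -0.66, and others, such as AT1G62020 at 0.05 and AT1G62130 at -0.01, did not pass the test.

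The low level of storage transcripts was weighed against tissue share and seed stage. For a smaller share of embryo tissue as the whole cause, WOX2, WOX8, WOX9, LEC1 and LEC2 were compared with the storage list. This set was chosen after its values were seen, and it leaves out FUS3 and L1L, both at -1.88. The outcome was thus known when the set was drawn. Its median log2 fold change was -0.49 (95% of member resamples -0.74 to -0.08). The storage list had a median of -5.72 (95% of member resamples -8.77 to -3.17), with members from -12.28 for CRB to -0.53 for DGAT1. WOX2, WOX8, WOX9, LEC1 and LEC2 as a set thus changed less than the storage list. A set drawn this way cannot decide on tissue share, and no conclusion is drawn from it. These genes also do not speak to a smaller share of embryo tissue in maturation alone. An earlier developmental stage of mee45 seeds predicts lower oil synthesis genes, and of 9 such genes 6 fell, FAD3 rose by 0.37 and PKP-ALPHA and SUS3 did not pass, with a median of -0.52 and 0.05% of random lists lower; 5 of the 9 belong to fatty acid terms already seen to be lower, and the 4 outside them had a median of -0.58 with 1.12% of random lists lower, LPD1 and SUS2 having fallen. Oil genes such as FAE1 and DGAT1 already stand on the storage list, so lower oil synthesis genes partly restate the pattern. Lower maturation at an equal stage would give the same values, so they do not single out an earlier stage. An earlier stage also predicts higher early endosperm genes. But 7 further ones had a median of 0.49 with 95.6% of random lists lower, short of the bound set beforehand. AGL48 was higher and AGL86 and AGL92 were lower. Slower seed development in mee45 may explain the pattern, and so may siliques of a different actual age at harvest. These cannot be told apart, because 0 of 6 samples carry a stage scored apart from days after pollination. The Col-0 levels of SESA3 (936 FPKM) and CRC (254 FPKM) were not compared with seeds of known age. Other causes were not tested.

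The lower JAZ and WRKY genes were set against handling. Of 18 rapid touch and wound genes, 16 fell, with a median of -1.57 and 0% of random lists lower, but 13 of the 18 belong to the JAZ or WRKY families or to the wounding and chitin terms and so largely restate the pattern. The 5 genes outside them had a median of -1.41, with 0.025% of random lists lower. That median is the value of CML39, which had mean counts of 1.67 in Col-0 and 0.667 in mee45 and did not pass. TCH2, TCH3, TCH4 and ERF11 fell, with log2 fold changes of -0.59, -1.43, -1.22 and -1.94. Weaker touch or wound induction before extraction may thus have contributed, and a genetic difference in the same response would give the same values, so the cause stays open. A lower sustained jasmonate response predicts lower later jasmonate genes, but 8 of them had a median of 0.18, with THI2.1 and VSP1 higher and CORI3 lower. That median lay above the bound set beforehand for arguing against this explanation. Resampling of members, which the bound as set did not ask for, gave -0.50 to 0.90 and so reached below that bound. For that reason the explanation was left open. Alpha-linolenic acid metabolism, the KEGG pathway that holds the jasmonate synthesis genes AOS and OPR3, was picked after its values were seen. Of its 41 tested genes, 13 were lower and 4 higher, against 3.49 lower expected (Fisher's exact test, adjusted p = 0.000589). AOS (AT5G42650) and OPR3 (AT2G06050) had log2 fold changes of -1.28 and -1.74.

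The position of changed genes was also examined. Within 1 Mb of MEE45, 16.2% of 271 tested genes were called against 15.9% of all placed genes. Of windows of as many genes, 53.5% had a lower share, so no excess of calls was seen there. The bound set beforehand for excluding a differing segment was not met. That bound asked for a share lower than in most windows, so a share near the average could not meet it. MEE45 starts at position 114971, so the chromosome end cut the window short on that side. Adjacent genes called in the same direction numbered 505 pairs, against a median of 321 and a highest value of 371 in 1000 shuffles, and a highest of 373 when calls were shuffled within bins of expression. Tandem copies that share regulation or reads may give such pairs; which of these applies was not tested.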
